A study of Mus musculus with 6 samples.

How the data were processed

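RNA was measured in 344SQ cells, a mouse lung adenocarcinoma line grown from a subcutaneous metastasis of an animal with an activated K-ras allele and a mutant p53 allele. The cells had been transduced with a lentivirus that carried either the microRNA cluster miR-200b-200a-429 or no microRNA, and GFP-positive pools were kept under puromycin. Each kind of cell was grown as 3 cultures, called here control A, B and C and miR-200 A, B and C, and each culture gave 1 array. The labels do not say that the cultures of one kind came from separately transduced pools, so the p-values measure the spread between these cultures. A stable difference between the transduced pools that has nothing to do with the microRNAs would enter every comparison below.

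The values are log2 signals, 1 per probe set and array, as deposited by the authors. Per the labels, biotin-labelled cRNA was hybridized to Affymetrix mouse expression arrays. The labels name the smaller 430A 2.0 design, whereas the deposited table holds 45101 probe sets and the probe annotation is that of the larger whole-genome design of the same family; the table was used as it stands. How probe signals were summarised and normalized is not given in the sources used here. The log base follows from the values, since 2 raised to each value is a number with 2 decimals, and between 1578 and 1718 probe sets per array lie exactly at 0, a floor. There are no detection calls in the table used. As a gauge of background, chosen after the data were examined, the highest value among the control probe sets for a bacterial trp gene was taken, 5.28 on the log2 scale after normalization. Where the dimmer group's mean lay under that level, the fold is given as "at least", the brighter mean over that level. The precision of the group means and of the variance estimates is limited by the number of arrays, 3 per group.

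A rule fixed before the data were examined took the table as normalized only if array medians and interquartile ranges each lay within 0.1 of each other. The medians spanned 0.0921 and the interquartile ranges 0.172, so the arrays were quantile normalized with limma 3.58.1 in R 4.3.3. The 64 control probe sets were then left out, which left 45037. Of these, 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 are not listed with one. Of the first kind, 34741 were matched by gene number to the RefSeq gene table of the GRCm38.p6 assembly, which supplied current symbols. A gene is represented by its brightest probe set over the 6 arrays among those with that symbol alone, which gave 18193 genes.

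The comparison is miR-200 minus control vector, fitted with limma (lmFit and eBayes, two-sided) with no further term, and p-values were adjusted by the Benjamini-Hochberg method over all 45037 probe sets with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 14 lists written before the data were examined from general knowledge. They hold 555 symbols, 525 of which were measured by a probe set with that symbol alone, and the others were not analysed here. The lists are miR-200 targets from the literature, epithelial genes, mesenchymal genes, extracellular matrix, the TGF-beta pathway, the Notch pathway, actin cytoskeleton and adhesion, chemokines with cytokines and angiogenic factors, interferon response, cell cycle, hypoxia and glycolysis, Ras-MAPK and p53 response, lung epithelial differentiation, and stromal and blood cell markers. The rule for named genes, also fixed in advance, takes the 12 largest rises and 12 largest falls among genes past the threshold whose 3 miR-200 values all lie on one side of the 3 control values. It adds up to 4 such members of each list and, whatever their values, Zeb1, Zeb2, Cdh1, Epcam, Vim, Cdh2, Fn1, Snai1, Crb3 and Esrp1.

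Alternatives fixed in advance were the values as deposited, centring on array medians, leaving out the dimmest 40% of probe sets, the mean of a gene's probe sets, a variance trend with robust estimation, array weights, the replicate letter as a block, each array left out, a minimum absolute log2 change of 1, camera with an estimated correlation, and fry. After the data were examined, 3 more were added because control B and miR-200 A stood apart, namely a 2-level term for those arrays, both arrays left out, and that term with the dimmest 40% left out. Because the term was read from the same expression values that are tested, its p-values are too small by an unknown amount. A planned comparison of genes with and without miR-200 seed sites was not run, because 3' UTR sequences were not used here.

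The fit was tested on simulated arrays with the real probe sets' means and spread and 200 changed probe sets among 45037. It found 8% of the 100 simulated log2 changes of 1 and 78% of the 100 of 3, and 10.4% of its calls were unchanged probe sets. With a smaller spread than the real one it found 89% and 100%. No call was made in simulated arrays without any change. The simulated noise was drawn independently for each probe set and array. In the real arrays the deviations of control B and miR-200 A from their group means correlated at 0.71. The simulated rates are therefore not error rates of the real data.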

Results

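Gene expression was measured on 6 arrays, 3 of 344SQ lung adenocarcinoma cells with a control vector and 3 of the same cells made to express the miR-200b-200a-429 cluster. The comparison asks which transcripts differ when this microRNA family, known as a repressor of the epithelial-mesenchymal transition factors Zeb1 and Zeb2, is forced on in a highly metastatic line. Values are log2 signals after quantile normalization, given as mean ± SD with n = 3, and changes are miR-200 minus control with the standard error of the limma fit. The microRNAs themselves were not analysed here.

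A small set of epithelial genes rose in the miR-200 cells, 6 of the 53 measured. Esrp1, a splicing factor of epithelial cells, went from 2.95 ± 0.47 to 9.26 ± 0.37, at least 15.8-fold higher (limma, adjusted p = 0.00389). Of the tight junction claudins, Cldn7 and Cldn3 rose by 4.24 ± 0.36 and 3.93 ± 0.29 (log2 ± SE), with adjusted p of 0.0162 and 0.0112, and all 4 probe sets of Cldn3 passed. Cldn4, under the background gauge in the control cells, was at least 15.6-fold higher (adjusted p = 0.0217). Rab25, a small GTPase of epithelial membrane recycling, was at least 7.96-fold higher (adjusted p = 0.00776). Of the 53 epithelial genes measured, 6 rose and 0 fell past the threshold over all probe sets, and 11 rose and 1 fell when adjusted over the list alone. The list's median log2 change was 0.15 and camera gave an adjusted p = 0.00830 (adjusted p = 0.947 with an estimated correlation). The list call was also lost without miR-200 A (adjusted p = 0.0923).

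Most epithelial genes did not pass the test, among them the splicing factor gene Esrp2 (0.13 ± 0.40, adjusted p = 0.923) and the tight junction gene Ocln (0.50 ± 0.41, adjusted p = 0.655), both chosen after their values were seen. Cdh1, which encodes E-cadherin, was already high in the control cells at 13.23 ± 0.13 and read 13.32 ± 0.12 in the miR-200 cells (adjusted p = 0.804). The polarity gene Crb3 read 9.16 ± 0.34 and 8.96 ± 0.41 (adjusted p = 0.794). The probe sets of Epcam, an epithelial adhesion molecule, disagreed. The brighter one, which represents the gene, differed by 0.42 ± 0.16 (adjusted p = 0.344), whereas the other went from a mean of 6.32 to 11.70, a difference of 5.38 ± 0.74 with an adjusted p = 0.0546. The mean of both probe sets differed by 2.90 and passed (adjusted p = 0.0414).

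Cdh2, the mesenchymal cadherin N-cadherin, fell. Its value went from 10.17 ± 0.47 to 6.27 ± 0.21, a log2 change of -3.90 ± 0.28 and 14.9-fold lower (adjusted p = 0.00985), and both of its probe sets passed. It was the single member past the threshold of 33 mesenchymal genes measured, with 0 higher; adjusted over the list alone, 3 were lower and 0 higher. The list as a whole did not pass (median -0.02, adjusted p = 0.756). The intermediate filament gene Vim read 13.77 ± 0.13 and 13.66 ± 0.06 (adjusted p = 0.753), fibronectin Fn1 11.13 ± 1.02 and 11.81 ± 0.51 (adjusted p = 0.663), and the transcription factor Snai1 5.87 ± 0.51 and 5.54 ± 0.27 (adjusted p = 0.683).

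Zeb1 and Zeb2, the best known targets of the family, had lower values in all 3 miR-200 cultures without passing the threshold. Zeb1 read 8.89 ± 0.32 and 7.80 ± 0.57, a difference of -1.08 ± 0.34 (adjusted p = 0.255). Zeb2 read 8.30 ± 0.13 and 7.45 ± 0.37, a difference of -0.85 ± 0.22 (adjusted p = 0.195). Both passed in 1 setting, chosen after the data were examined, with a term for the 2 arrays described below and without the dimmest 40% of probe sets (adjusted p = 0.00483 and 0.00989). None of the other probe sets of either gene passed, and some had differences above 0, such as 0.31 ± 0.14 for a probe set of Zeb2. Of 36 targets from the literature, 0 passed over all probe sets. At an unadjusted p under 0.05 in limma, 5 were higher and 7 lower, against 6354 of 45037 probe sets on the whole array. The fit found only 8% of simulated log2 changes of 1, so the lack of calls does not show that no target fell. Adjusted over the list alone, 1 was higher and 4 were lower. The list did not pass (median -0.0039, camera adjusted p = 0.756).

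**Figure D1:**
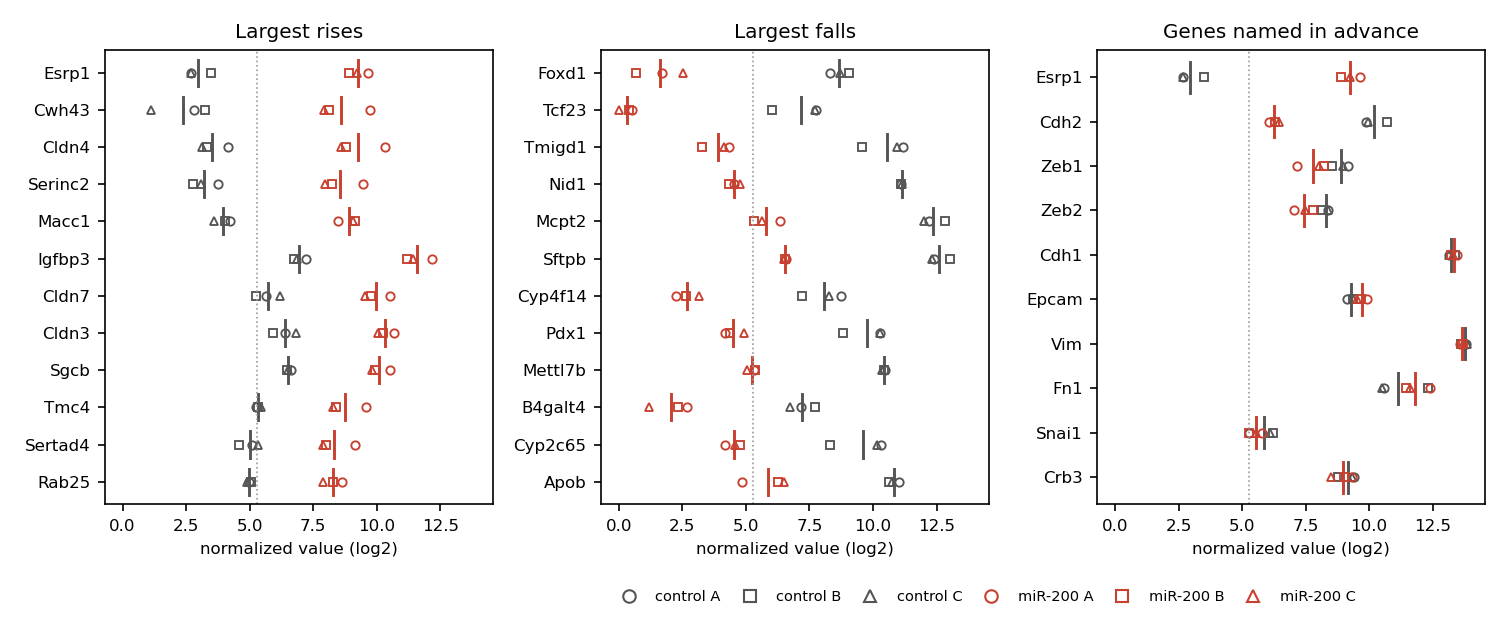
Normalized log2 values of the genes with the largest rises, the largest falls and the genes named in advance; each symbol is 1 array, bars are group means of 3 arrays, and the dotted line is the background gauge of 5.28. Esrp1 is higher and Cdh2 lower in all 3 miR-200 cultures, while Cdh1 and Vim overlap.

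Nid1, a basement membrane protein that links laminin and collagen IV, fell from 11.12 ± 0.02 to 4.54 ± 0.21, at least 57.4-fold lower (adjusted p = 0.00111). Its other probe sets were dimmer and differed by less, -2.79 (adjusted p = 0.00982) and -1.24 (adjusted p = 0.334), with miR-200 means under the background gauge, and the mean of all 3 differed by -3.54 (adjusted p = 0.00424). Nid1 was the only one of 42 matrix genes past the threshold, over all probe sets and when adjusted over the list alone, and the list did not pass (median 0.07, mean -0.01, adjusted p = 0.875). Of 32 lung epithelial genes, 2 fell. Sftpb, which encodes surfactant protein B, went from 12.58 ± 0.38 to 6.54 ± 0.03, 65.6-fold lower (adjusted p = 0.00249). The water channel Aqp5 went from 12.31 ± 0.07 to 10.85 ± 0.06, 2.75-fold lower (adjusted p = 0.0148). Adjusted over the list alone, 1 lung gene was higher and 5 were lower, and the list did not pass (median -0.13, adjusted p = 0.722).

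The remaining large falls came from genes of varied function. The transcription factor genes Foxd1, Tcf23 and Pdx1 were at least 10.6-fold, 3.70-fold and 22.6-fold lower, with adjusted p of 0.00985, 0.0121 and 0.0179; the dimmer Pdx1 probe set differed by -3.21 without passing (adjusted p = 0.0958). The mast cell protease gene Mcpt2 was 95.4-fold lower (adjusted p = 0.00450). Apob, which encodes the apolipoprotein of chylomicrons and low-density lipoprotein, was 31.0-fold lower (adjusted p = 0.0201), and its other probe set did not pass. The miR-200 means of Mcpt2 and Apob, 5.77 and 5.85, lay close to the gauge of 5.28, and Apob read 4.83 on miR-200 A. The folds of both genes are therefore less certain. Tmigd1 and Mettl7b were at least 39.0-fold and 35.4-fold lower, with adjusted p of 0.0125 and 0.00111. The cytochrome P450 genes Cyp4f14 and Cyp2c65 were at least 6.97-fold and 19.9-fold lower, and B4galt4, a galactosyltransferase gene, at least 3.81-fold, with adjusted p of 0.0166, 0.0384 and 0.0192. Among the rises, Igfbp3, which binds insulin-like growth factors, was 25.2-fold higher (adjusted p = 0.00776) and Sgcb, a sarcoglycan gene, 11.9-fold higher (adjusted p = 0.00665). Cwh43, Serinc2, Macc1 and Sertad4 were at least 9.83-fold, 9.76-fold, 12.2-fold and 8.31-fold higher. Tmc4, with a control mean of 5.34 close to the gauge, was 10.6-fold higher. Adjusted p for Cwh43, Serinc2, Macc1, Sertad4 and Tmc4 ranged from 0.00450 to 0.0419.

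In the chemokine, cytokine and angiogenic list 1 of 41 members passed, Angptl4, which encodes a lipoprotein lipase inhibitor and was 4.42-fold lower (adjusted p = 0.0275). Its other probe set, under the background gauge in both groups, differed by -0.30 (adjusted p = 0.802), and the mean of both did not pass (-1.22, adjusted p = 0.168). In the hypoxia and glycolysis list 1 of 28 passed, the oxygen sensor gene Egln3, 3.59-fold lower (adjusted p = 0.0310). Adjusted over the list alone, 4 chemokine and angiogenic genes were higher and 3 lower, and 0 hypoxia genes were higher and 2 lower. Neither list passed (adjusted p = 0.875 and 0.722). No member passed among 31 TGF-beta, 26 Notch, 43 actin and adhesion, 42 interferon, 49 cell cycle, 34 Ras-MAPK and p53, and 35 stromal and blood cell genes. In the order just given, the counts at an unadjusted p under 0.05 were 3 higher and 6 lower, 2 and 3, 6 and 1, 0 and 5, 0 and 0, 4 and 3, and 3 and 1. Adjusted over the list alone, 3 TGF-beta genes were higher and 4 lower, 1 Notch gene was higher, 1 interferon gene was lower, and 0 passed in the other 4 lists. Their camera adjusted p were 0.875, 0.875, 0.722, 0.190, 0.722, 0.932 and 0.426. The test and the median differed in sign for the TGF-beta, hypoxia and Ras lists, and the mean and the median for the matrix, TGF-beta, Notch and hypoxia lists.

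**Figure D2:**
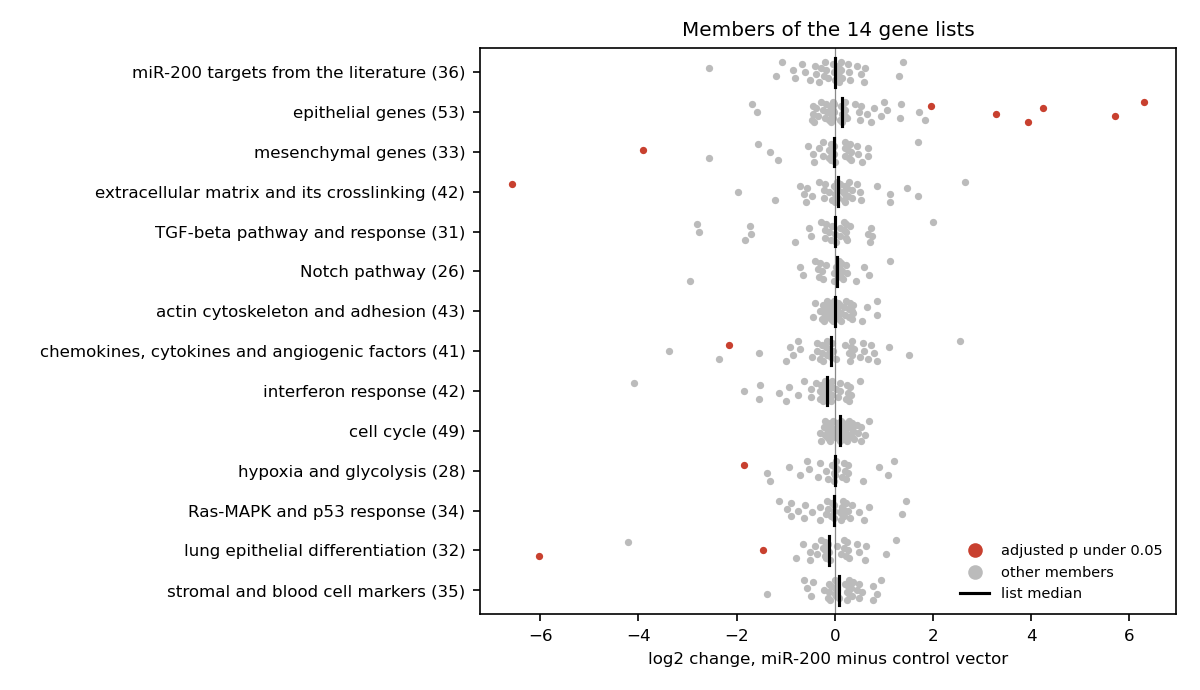
Log2 change, miR-200 minus control, of every measured member of the 14 gene lists, with the number of members in brackets; each point is 1 gene, red points have an adjusted p under 0.05, and black bars are list medians. The epithelial list has 6 red points to the right, while its median is 0.15.

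Across the array, 335 of 45037 probe sets passed, 116 higher and 219 lower, and 172 of 18193 genes, 50 higher and 122 lower. All 172 had groups that did not overlap, as did 4280 genes in all (23.5%, against 10% by chance). In none of them did probe sets pass in opposite directions. The median log2 change of all genes was 0.0014, and -0.07 after centring on array medians.

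Control B and miR-200 A stood apart from the other arrays of their groups. The correlation of their deviations from the group means, across the brightest 60% of probe sets, was 0.71. The median of the 49 cell cycle genes was 8.54 on control B and 8.65 on miR-200 A, and 10.90, 10.90, 11.02 and 11.11 on control A, control C, miR-200 B and miR-200 C. The chemokine list had its highest medians on the same arrays, 7.88 and 8.07, against 6.98 to 7.12 elsewhere. Without both arrays, 103 probe sets and 57 genes passed. With a 2-level term for them, chosen after the data were examined, 946 probe sets and 480 genes passed, and the interferon list (lower, adjusted p = 0.0131) and the cell cycle list (higher, adjusted p = 0.0292) passed too. With an estimated correlation in that same fit neither list passed (adjusted p = 0.548 for interferon and adjusted p = 0.883 for cell cycle). Leaving out control A left 32 probe sets and leaving out miR-200 B left 40.

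**Figure D3:**
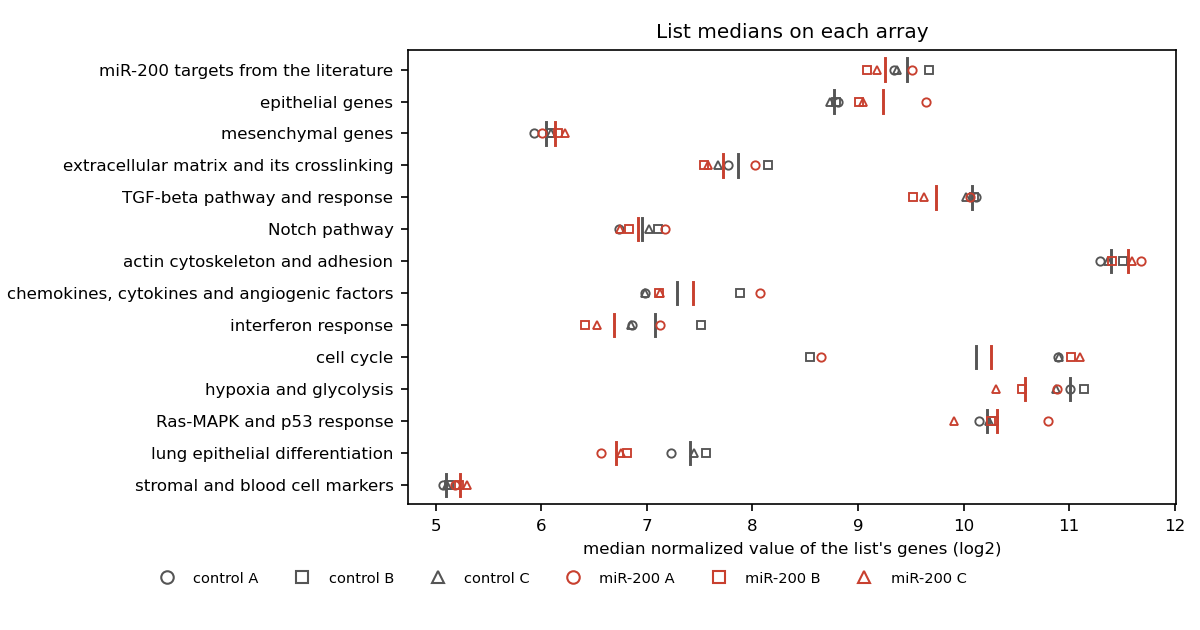
Median normalized log2 value of each gene list on each array; each symbol is 1 array and bars are the means of 3 arrays. On the cell cycle list control B (8.54) and miR-200 A (8.65) lie below the other 4 arrays, which lie between 10.90 and 11.11.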

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

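The alternatives that treat the arrays that stand apart were chosen after the data were examined; the others were fixed before. All 28 named genes past the threshold kept their direction under every alternative that measured them, and all were past it as deposited, after centring, with the variance trend and with array weights. With the mean of a gene's probe sets 27 passed and Angptl4 did not (-1.22, adjusted p = 0.168), without both arrays that stand apart 10 passed, and with the replicate block 0. Without the dimmest 40%, 23 of them were measured and all passed, with or without the term. In the settings without 1 array, between 5 (without control A) and 24 (without miR-200 A) of them passed. The number of calls depended strongly on the setting. The 335 probe sets and 172 genes became 923 and 476 without the dimmest 40%, 951 and 494 with the variance trend, and 1291 and 606 with array weights. They became 946 and 480 with the 2-level term, 4606 and 2271 with that term and without the dimmest 40%, and 103 and 57 without both arrays. The balance of directions moved as well. Of the probe sets, 18 were higher and 85 lower without both arrays, and 2169 and 2437 with the term and without the dimmest 40%. Without 1 array they ranged from 32 to 328 and from 16 to 184, lowest without control A and highest without miR-200 A. Without control B, control C, miR-200 B and miR-200 C, 139, 57, 40 and 54 probe sets passed. The mean of a gene's probe sets gave 268 genes. Fewer probe sets tested and fewer arrays act in part by construction. Without the dimmest 40%, the adjusted p of Esrp1 in limma went from 0.00389 to 0.000426. That is a larger drop than the change from 45037 to 27022 tests alone can bring. The variances were also estimated anew from the probe sets kept. Otherwise the cause was not tested.

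With the letter as a replicate block, 0 probe sets and 0 genes passed in limma, against 4280 probe sets at an unadjusted p under 0.05. The fit without a block has only 4 residual degrees of freedom, and the block uses up part of them. Control B and miR-200 A carry different letters, so the block cannot absorb all of their shared deviation. The loss of calls alone therefore does not argue against the changes. The deviations of arrays with the same letter correlated at -0.58, -0.67 and 0.43 for A, B and C, and not every array correlated best with its own letter. Deviations within a group cancel out by construction, and those of control B and miR-200 A were the largest. These correlations therefore cannot show whether the letters pair the cultures.

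The epithelial list was past the threshold in the reported setting and lost its call with array weights (median 0.14), without both arrays (0.18), with an estimated correlation (adjusted p = 0.947) and with fry (adjusted p = 0.0710); without 1 array its median ranged from 0.052 to 0.18, and the call was lost without miR-200 A. Centred on array medians its median was 0.040, with the call kept (adjusted p = 0.00851). The interferon list gained a call with the 2-level term (median -0.16) and ranged from -0.37 to -0.021 without 1 array, with a call without control A and without miR-200 A. With an estimated correlation its adjusted p = 0.548 with the term, and adjusted p = 0.911 and 0.697 without those arrays. The cell cycle list gained one with the term (0.11) and without both arrays (0.15), and ranged from -0.67 without control B to 1.02 without miR-200 A, where it also had a call. With an estimated correlation its adjusted p = 0.883 with the term, and adjusted p = 0.747 and 0.697 without both arrays and without miR-200 A. Across 252 list results under alternatives, 44 changed the sign of the median, 0 of them with a call in either setting. The literature targets had 0.0014 without the dimmest 40%, with or without the term. TGF-beta had -0.023 as deposited, -0.094 centred, -0.037 without the dimmest 40% with or without the term, and -0.016 with array weights. Notch had -0.027 centred, -0.00084 with array weights and -0.024 without both arrays, and actin -0.069 centred. Hypoxia had -0.034 as deposited, -0.11 centred, -0.079 with array weights and -0.083 without both arrays, and Ras 0.00079 without both arrays. Without 1 array the medians ranged from -0.056 to 0.019 (targets), -0.076 to 0.030 (mesenchymal), -0.095 to 0.17 (TGF-beta), -0.077 to 0.086 (Notch), -0.053 to 0.064 (actin), -0.27 to 0.15 (chemokines), -0.16 to -0.0083 (hypoxia), -0.065 to 0.060 (Ras) and -0.17 to 0.0089 (lung). The cause was not tested. Zeb2 ranged from -1.02 to 0.23 and Crb3 from -0.40 to 0.23 without 1 array. Zeb2 was positive without control A, where another probe set became the brightest; the reported one differed by -0.82 there. Crb3 was positive for the same reason without control A and without control C (-0.095 and -0.12 for the reported probe set), and at 0.013 without miR-200 C on the reported probe set. The same switch gave Epcam 5.03 without control A and 4.92 without control C, neither past the threshold, and the mean of its probe sets passed at 2.90. Zeb1 and Zeb2 gained a call with the term and without the dimmest 40%. The seed site comparison was not run, and pseudocounts do not apply to log2 values. For 53 of the 172 genes the dimmer group's mean lay under the background gauge, which limits their folds.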

Other observations

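All tests in this part other than the counts of splits were chosen after the results were seen.

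Several genes with the largest falls, Pdx1, Apob, Cyp2c65 and Cyp4f14, are known from the gut, pancreas or liver. The hypothesis that a gut and liver programme is lower in the miR-200 cells was tested on 1 list of other gut and liver genes, written for the purpose without the genes named above. Of 49 measured, 33 were lower, by any amount, and the median log2 change was -0.14. Camera gave p = 0.00275, and p = 0.0378 with an estimated correlation; fry gave p = 0.00568, and without 1 array camera's p ranged from 0.00107 to 0.0158. No member passed in limma by its representative probe set (0 higher, 0 lower), though the other probe set of Fabp1 did, lower. Fabp1, which encodes a fatty acid binding protein, had an adjusted p = 0.0571 by its representative. With the 2-level term, whose p-values are too small, Fabp1 (limma, adjusted p = 0.0257) and Tff1 (adjusted p = 0.0399) passed by their representatives. Of the list, 12 lay under the background gauge in both groups. The 3 most negative changes, chosen after they were seen, among members above the background gauge in both groups were those of the keratin Krt20 (-2.83, adjusted p = 0.182), the alpha-fetoprotein gene Afp (-2.31, adjusted p = 0.0649) and the trefoil factor gene Tff1 (-2.16, adjusted p = 0.0854). Fabp1, under the gauge in the miR-200 cells, was at least 2.62-fold lower. Several liver genes above the gauge in both groups, also chosen after they were seen, moved little. They were Alb (-0.04), Apoa1 (-0.01), Apoa2 (-0.17) and Apoh (0.14), whereas Foxa3 differed by -0.59 without passing. The control means of Alb, Apoa1, Apoa2 and Apoh, 6.73, 5.65, 5.84 and 6.57, lay close to the gauge of 5.28. They had little signal to lose, so their small changes say little about liver genes. The shift has the direction of the hypothesis. The list was prompted by falls seen on these same arrays, so the shift is not independent support. It does not show that the liver genes fell as a set. A lasting difference between the transduced pools was not tested and stays open.

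Control B and miR-200 A stood apart from the rest of their groups. The labels give no group that separates these cultures, so no biological explanation was tested. A swap of their labels is argued against by Esrp1, which was 6.16 higher on miR-200 A than on control B, or at least 4.36 when control B, under the background gauge, is set to it, and by Cdh2, which differed by -4.67. The spiked hybridization controls had means of 10.92 and 10.88 on these arrays and 10.70 to 10.96 on the others, so they showed no fault of hybridization. How the deposited values were normalized is not known, and scaling could have removed a difference in scanning. The controls therefore cannot exclude one. RNA degradation stays open: the 3' minus 5' difference of the transferrin receptor controls was 1.25 on both, under the 1.27 of control A, but that of the nearly saturated actin controls was highest on these arrays, 0.19 and 0.24 against 0.09 to 0.13. That of the Gapdh controls, -0.29 and -0.28, lay inside the -0.29 to -0.26 of the others.

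On miR-200 C the spiked poly-A controls averaged 7.80, against 8.73 to 8.84 on the other arrays.

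Dividing the 6 arrays 3 against 3 gives 10 splits, too few for a share under 0.05. The labelled split called 335 probe sets and 172 genes, and the highest of the others called 2 and 1; 1 of the 10 splits called as many. For gene lists the labelled split called 1 and the highest other split 5. At least as many lists as in the labelled split were called in 6 of the 10 splits. These calls used camera's preset correlation of 0.01. The correlations estimated in the labelled split ranged from -0.027 for the mesenchymal list to 0.977 for the cell cycle list. Splits with control B and miR-200 A on the same side called between 3 and 5 lists. The other unlabelled splits called 0, except that of control A, miR-200 A and miR-200 C against the rest, which called 3. The high counts therefore mostly went with the side on which control B and miR-200 A fell. Whether the preset correlation also made the p-values too small was not tested. The gut and liver list had its lowest camera p in the labelled split, with 0.0174 and 0.0356 as the next lowest. That list was prompted by falls seen in the labelled split, so its rank there is not independent support.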
